A study of Mus musculus with 12 samples.

How the data were processed

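Total RNA of mouse bone marrow derived macrophages was extracted with a column kit, made into libraries with a NEBNext Ultra kit and sequenced on an Illumina NovaSeq instrument as paired reads of 51 bases, per the labels' protocols. The submitters' processing notes name bcl2fastq, Salmon 1.2.0 and the genome build mm10. How transcripts were summed to genes, the annotation release and the handling of strand are not given in the sources used here. The authors deposited 1 table with a column per library and TPM values for 23438 Ensembl gene IDs. TPM divides the estimated reads of a gene by its effective length and scales each library to a fixed total, so a rise of abundant transcripts lowers the values of all others. The 23438 listed genes summed to between 940127 and 947987 TPM per library, so a part of each library lay on genes outside the table. TPM keeps no depth: the number of reads behind a value is unknown, and no counting interval or detection limit was computed. Genes with near-identical partners share reads that Salmon divides between them by its model, so the levels of such genes are uncertain.

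Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38 (mm10), with 23423 of the 23438 IDs matched to a symbol. Each column was assigned to its library through the submission name in the library descriptions, and the genotype was taken from the labels. No 2 libraries held identical values. The closest pair (WT replicates 1 and 7, Pearson correlation 0.996 across genes) still differed by more than 1.5-fold on the log2(TPM + 1) scale in 145 genes, so all 12 libraries were counted as separate. Replicate numbers 1 to 5 occur in both genotypes, but no label ties same-numbered libraries together.

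The test planned before the data were examined was for counts, with a stated alternative for TPM, and the alternative was used because the table holds TPM. It was limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), that is with a pseudocount of 1, over the 11152 genes with at least 1 TPM in at least 5 libraries. Genotype was the only term, and p-values were adjusted by the Benjamini-Hochberg method over these genes, with 0.05 as the threshold. Fold changes are on the log2(TPM + 1) scale and understate the change of genes at low levels. Errors of fold changes are standard errors from limma, and errors of levels are SDs. The fits were tested on simulated data with the mean and residual spread of each gene, drawn independently per gene, in which 200 of the 11152 genes were changed. With all 12 libraries, 70% of the genes changed by 1.5-fold, 86% of those changed by 2-fold, 96% of those changed by 4-fold and 98% of those changed by 8-fold were called. False calls were 5.91% of all calls. With the 9 libraries named below, the shares were 88%, 96%, 100% and 100%, with 4% false calls. The changed genes were drawn from those at higher mean levels, so recovery at low levels is unknown. Every library was given the same spread per gene, so WT libraries that stand apart together were not simulated. The shares and false calls may therefore not hold for the real libraries.

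A total of 48 gene lists covering chromatin remodelling, mitochondria, metabolism, lipid handling, inflammation, stress responses and markers of cell types were fixed before the data were examined, and 46 had at least 2 tested genes. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with the correlation estimated per list and the rotation test fry as alternatives. Listed genes whose symbol had no match in the table were not analysed here. Principal components were computed from the 500 genes with the largest variance, after centring. Component scores and the share of TPM from the mitochondrial genome were compared by exact two-sided permutation tests over all 792 splits of the 12 libraries into groups of 7 and 5. The genes named in the text follow a rule fixed before the data were examined. They are Smarcd1, Smarcd2, Smarcd3 and Lyz2, then the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 TPM in the higher group. Predicted or unnamed genes and pseudogenes were left out of these. Up to 3 called members per list and direction follow, or up to 2 members as values only where none was called. The marker genes given per library, Txnrd1, Cat and the genes of the additional observations were chosen after their values were seen.

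The alternatives planned before the data were examined were other scalings, no filter, a pseudocount of 0.1, sample quality weights, leaving out each library, a replicate block, a submission block, and stricter thresholds. Count models were not used, since they need counts. A covariate for sex was not used, since Y-linked transcripts were present in all 12 libraries. Leaving out WT replicates 2, 3 and 4 together, a stromal marker covariate, the first component of the residuals as a covariate and a minimum of 5 TPM were added after seeing the data, as were all alternatives for the component scores and for the set of 9 libraries. The rule for named genes was applied to the set of 9 libraries in the same way.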

Results

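Messenger RNA levels were measured by RNA sequencing in macrophages grown from mouse bone marrow (bone marrow derived macrophages, BMDMs) and collected on day 7 of differentiation. The marrow came from C57 mice with atherosclerosis, the build-up of lipid-rich plaques in arteries. The labels gave 7 wild-type (WT) libraries and 5 libraries from Baf60a knockout (KO) macrophages, 12 in all. Baf60a is the protein encoded by Smarcd1, a subunit of the SWI/SNF (BAF) complex, which moves nucleosomes along DNA. The series states a single comparison, KO against WT. No label said whether the libraries came from separate mice, so the p-values measure the spread between these libraries, which may be partly technical. The deposited values were TPM, the share of transcripts of each gene in a library, corrected for gene length. TPM carries no sequencing depth, so no counting interval could be given. The labels put the depth at an average of 30000000 read pairs per library, 360000000 in all. Of the listed genes, 11152 reached 1 TPM in at least 5 libraries and were tested.

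The targeted gene was examined first. Smarcd1 (ENSMUSG00000023018, chromosome 15, 99702129 to 99713991 in mm10) was lower in the KO libraries, at 6.90 ± 0.579 TPM (SD, n = 5) against 13.6 ± 1.40 TPM (SD, n = 7) in WT. All 5 KO libraries lay between 5.99 and 7.58 TPM and all 7 WT libraries between 11.6 and 15.6 TPM. The log2 fold change on the log2(TPM + 1) scale was -0.88 ± 0.0801 (SE), with an adjusted p of 7.4e-04 in limma. About 0.542 of the WT level on that scale therefore remained in the KO libraries. The values are sums over the transcripts of a gene and do not show which exons the remaining transcripts hold. The 2 related subunit genes did not pass the threshold. Smarcd2 was at 58.7 ± 4.63 TPM (SD, n = 5) in KO and 50.7 ± 7.33 TPM (SD, n = 7) in WT, with a limma adjusted p of 0.286. Smarcd3 lay between 1.26 and 1.89 TPM in the KO libraries, between 0.97 and 1.97 TPM in 4 WT libraries, and at 10.1, 8.65 and 18.6 TPM in WT replicates 2, 3 and 4 (limma adjusted p of 0.32).

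**Figure D1:**
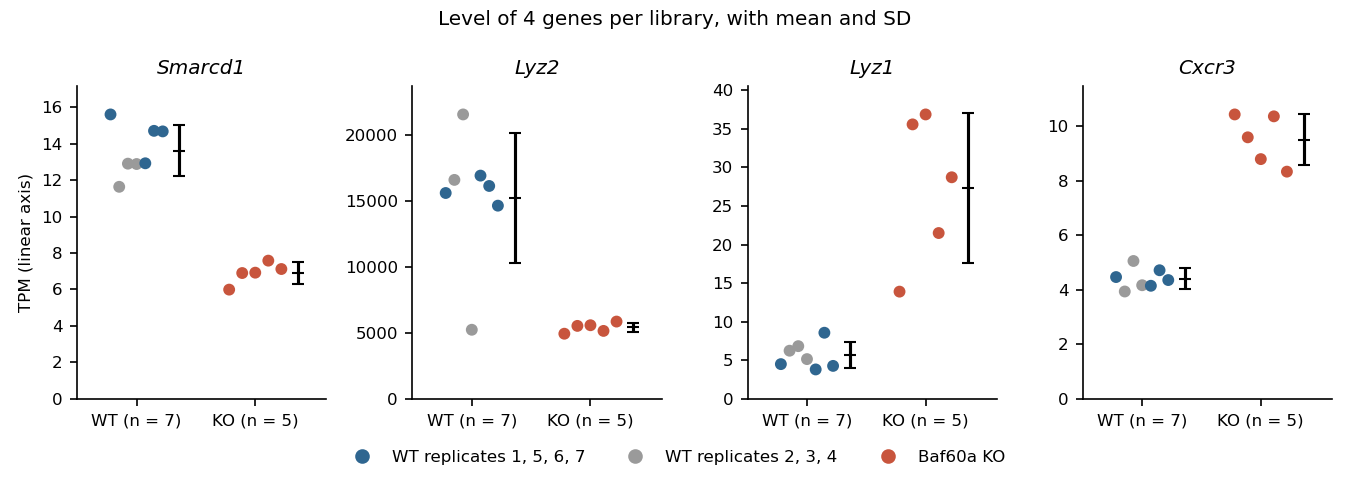
TPM of Smarcd1, Lyz2, Lyz1 and Cxcr3 on linear axes, 1 point per library, with the mean and SD of each genotype beside the points. The 5 KO libraries lie below all 7 WT libraries for Smarcd1 and above all 7 for Lyz1 and Cxcr3, while for Lyz2 WT replicate 4, at 5232 TPM, lies among the KO libraries.

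WT replicates 2, 3 and 4 differed from the other 9 libraries in the levels of many cell type markers. Marco, a scavenger receptor of macrophages, stood at 1569.9, 2043 and 1186 TPM in these libraries and at 0.13 to 2.64 TPM in the other 9. Transcripts of fibroblasts and smooth muscle were abundant in them. The collagen gene Col1a1 reached 480.4, 327 and 822 TPM there, against 15.7 to 73.3 TPM elsewhere. The actin gene Acta2 reached 2076, 1574 and 4236 TPM, against 42.3 to 215 TPM elsewhere. Several genes of macrophages and neutrophils were low in the same libraries. Csf1r, the receptor for macrophage colony-stimulating factor, was at 215, 275 and 169.6 TPM, against 541 to 910.1 TPM elsewhere. The complement gene C1qa was at 188, 474 and 146 TPM, against 2241 to 3113 TPM elsewhere. The neutrophil protein gene S100a9 was at 3.39, 6.82 and 26.1 TPM, against 536 to 3507 TPM elsewhere. Adgre1, which encodes the macrophage antigen F4/80, was at 449.8, 586 and 371 TPM, against 448 to 653 TPM elsewhere. Pearson correlations across genes (genes are not independent replicates) were 0.969 to 0.991 among these 3 libraries and 0.833 to 0.928 between them and the other 9. Among the other WT libraries they were 0.986 to 0.996, and among the KO libraries 0.982 to 0.995. The comparison was therefore made with all 12 libraries and, as an alternative chosen after seeing the data, with the 9 libraries left without these 3. Genes that passed the threshold with 9 libraries alone are given with those values, and with the 12-library value where the sign differed.

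**Figure D2:**
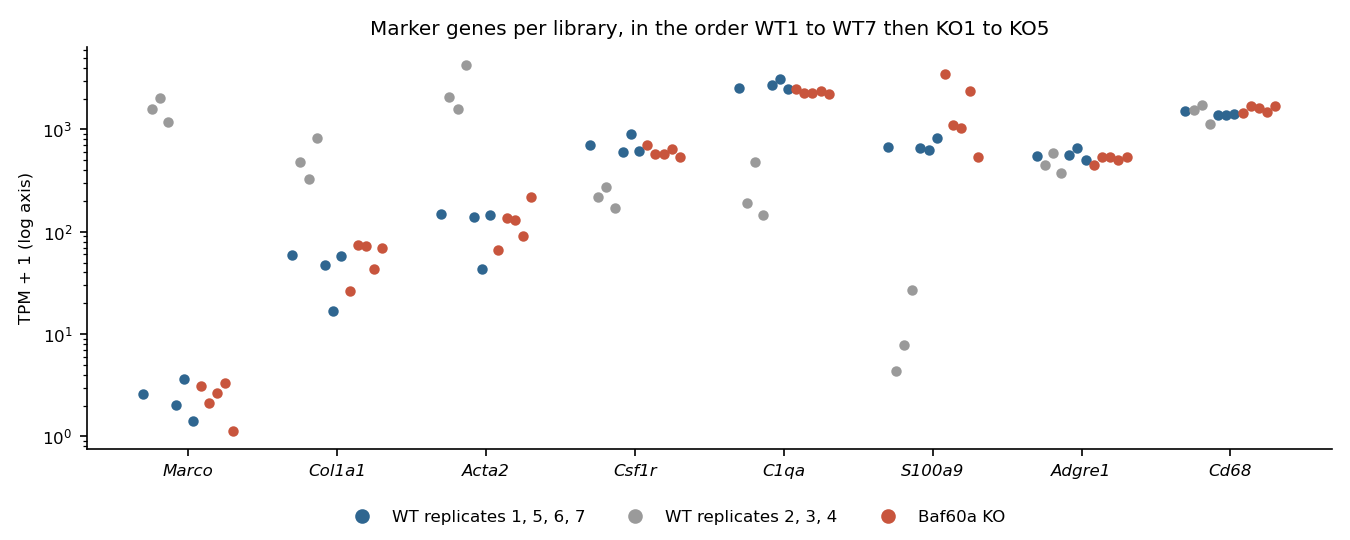
TPM + 1 of 8 marker genes on a log axis, 1 point per library, ordered within each gene from WT replicate 1 to 7 and then KO replicate 1 to 5. WT replicates 2, 3 and 4 (grey) lie above the other libraries for Marco, Col1a1 and Acta2 and below them for Csf1r, C1qa and S100a9.

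Principal components were used to ask how far genotype separates the libraries. Over all 12 libraries, component 1 held 89.2% of the variance of the 500 most variable genes. WT replicates 2, 3 and 4 scored 50.3, 42.5 and 63.4 on it, and the other 9 libraries between -30.6 and -9.15. The mean score of KO minus that of WT was -28.7 on component 1, -1.26 on component 2 and 5.23 on component 3. Exact two-sided permutation tests over all splits gave p = 0.136, 0.722 and 0.0871, or 0.205, 0.722 and 0.205 after adjustment over the 3. None of the 3 components separated the genotypes beyond the spread of the libraries. Without WT replicates 2, 3 and 4, component 1 held 41.7% of the variance and component 2 held 19.1%. The difference of mean score on component 2 was -12.2 in this set, with an exact permutation p of 0.00794, the smallest that 126 splits allow, and 0.0238 after adjustment. Components 1 and 3 of this set gave exact permutation p-values of 0.905 and 0.667. Leaving out only WT replicate 3 or only WT replicate 4 also gave 1 component past the threshold, with lowest adjusted exact p-values of 0.039 and 0.013.

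**Figure D3:**
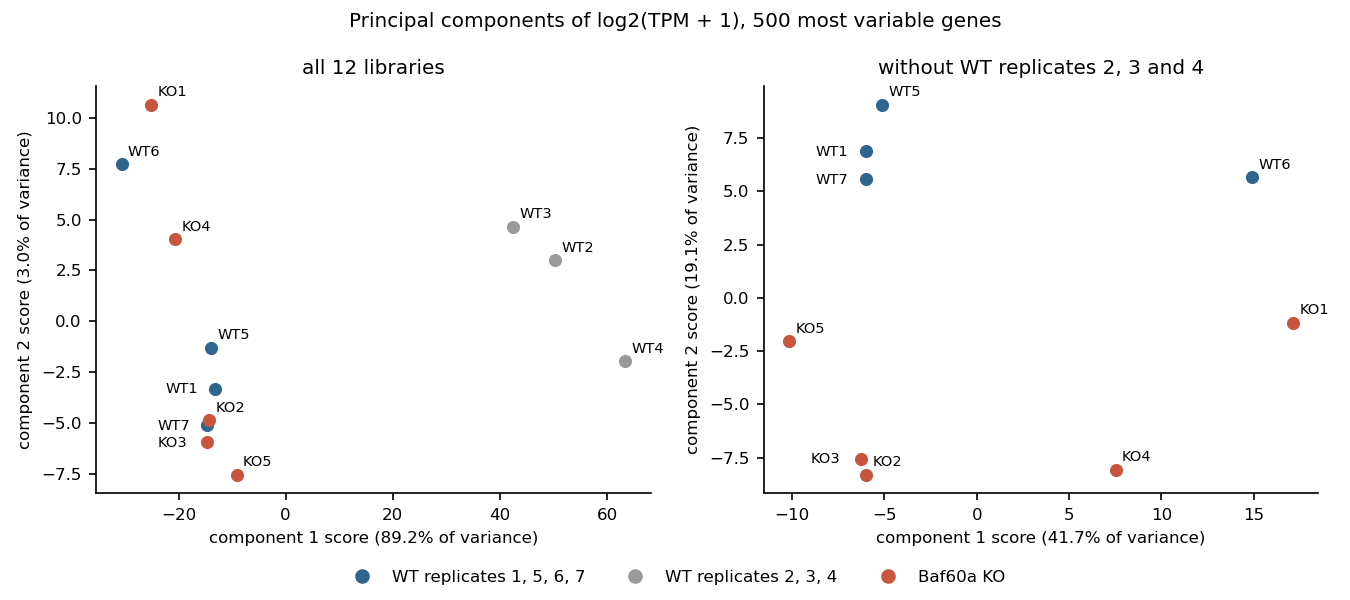
Scores of each library on components 1 and 2 of log2(TPM + 1) over the 500 most variable genes, for all 12 libraries (left) and for the 9 left without WT replicates 2, 3 and 4 (right). On the left these 3 libraries score 42.5 to 63.4 on component 1, and on the right the 4 WT libraries lie above the 5 KO libraries on component 2.

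With all 12 libraries, 14 genes differed between KO and WT, 12 of them higher and 2 lower in KO. Cxcr3, a chemokine receptor best known from T cells, rose from 4.41 ± 0.381 TPM (SD, n = 7) to 9.51 ± 0.933 TPM (SD, n = 5). Its log2 fold change was 0.96 ± 0.077 (SE), with a limma adjusted p of 4.1e-04. Lyz1, which encodes a lysozyme that breaks bacterial cell walls, rose from 5.62 ± 1.69 TPM (SD, n = 7) to 27.3 ± 9.69 TPM (SD, n = 5), a log2 fold change of 2.05 ± 0.244 (SE, limma adjusted p of 0.0089). Both genes for beta chains of the receptors for granulocyte-macrophage colony-stimulating factor and interleukin 3 rose. Csf2rb went from 57.2 ± 3.56 to 79.0 ± 8.32 TPM and its neighbour Csf2rb2 from 51.1 ± 4.82 to 70.2 ± 2.47 TPM (SD, n = 7 and n = 5), each by 0.46 on the log2 scale (limma adjusted p of 0.041 and 0.035). Csf2rb with Csf2rb2, and Lyz1 with Lyz2, are near-identical pairs, so reads could be split between partners and the level of each gene is uncertain. The small GTPase gene Rac3 rose by 0.60 on the log2 scale, from 11.6 ± 1.58 to 18.1 ± 0.803 TPM (SD, n = 7 and n = 5). The other risers, by 0.31 to 0.56 on the log2 scale, were Shtn1, Necap1, Mknk2, Snap23, Fem1c, Rchy1 and Cdkl2. Cdkl2 lay below the mean level of 5 TPM set for naming and was chosen after its values were seen. Besides Smarcd1, the gene that fell was Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, from 58.8 ± 4.62 to 44.9 ± 1.78 TPM (SD, n = 7 and n = 5), a log2 fold change of -0.38 (limma adjusted p of 0.041). At an unadjusted p under 0.05 there were 1954 genes.

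The number of genes called with all 12 libraries rested on single libraries. Smarcd1 and Cxcr3 were called whichever library was left out, and Lyz1 in 11 of the 12 cases (adjusted p of 0.0539 without KO replicate 5). The count was 4 without WT replicate 1, 4 without WT replicate 2, 3 without WT replicate 3, 4 without WT replicate 5, 36 without WT replicate 6 and 5 without WT replicate 7. It was 4, 4, 3, 3 and 2 without KO replicates 1 to 5, and 21 without WT replicate 4. Dividing each library by its median ratio to the gene-wise mean gave 4 genes, 2 higher and 2 lower, in place of 12 and 2. With a covariate for submission block (submission numbers 1 to 5 against 6 to 12) 3 genes stayed called, Smarcd1, Cxcr3 and Lyz1, while Csf2rb, Csf2rb2, Rac3, Gclc and the others lost their calls. The block was drawn from the order of the submission numbers, and no label used here names it as a batch. The block of replicate numbers, on 10 libraries, left 0 genes called by limma (3706 at an unadjusted p under 0.05), against 13 in the same libraries without it.

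Lyz2, the major lysozyme gene of macrophages (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), was fixed for reporting in advance. It was at 5406 ± 366 TPM (SD, n = 5) in KO and 15234 ± 4930 TPM (SD, n = 7) in WT, a log2 fold change of -1.40 ± 0.28 (SE) that missed the threshold (limma adjusted p of 0.111). WT replicate 4, at 5232 TPM, lay inside the KO range of 4932 to 5853 TPM, while the other WT libraries lay between 14635 and 21547 TPM. Without WT replicate 4, the log2 fold change was -1.64 and the limma adjusted p 4.0e-05. Lyz1 (chromosome 10, 117287797 to 117292868) lies beside Lyz2 and, at 13.9 to 36.9 TPM in KO, stayed far below it.

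Without WT replicates 2, 3 and 4, 260 genes differed between 5 KO and 4 WT libraries, 180 higher and 80 lower in KO. All 14 genes called with 12 libraries were among them, with the same sign. Of the 260, 213 had the same sign with all 12 libraries and 150 an unadjusted p under 0.05 there. Most changes were small: the median size among the 260 was 0.32 on the log2 scale, 41 genes changed by at least 1.5-fold and 7 by at least 2-fold. Leaving out a further library gave 51 (WT replicate 1), 125 (WT replicate 5), 462 (WT replicate 6), 72 (WT replicate 7), 316, 108, 102, 82 and 245 genes (KO replicates 1 to 5). With median-ratio scaling 221 genes were called, 83 higher and 138 lower, and 163 of the 260 were among them in the same direction. The split into higher and lower genes thus differs with the scaling. With the submission block as a covariate 132 genes were called, and 29 of the 57 named genes kept their calls.

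**Figure D4:**
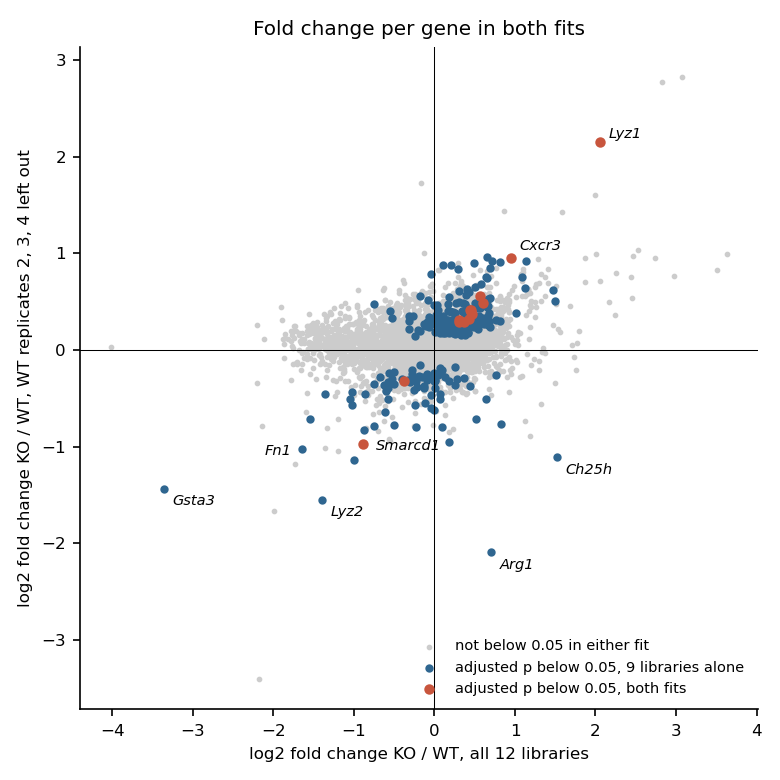
Log2 fold change of KO over WT for the 11152 tested genes, with all 12 libraries on the horizontal axis and without WT replicates 2, 3 and 4 on the vertical axis. Red points mark the 14 genes called in both fits and blue points the genes called with 9 libraries alone. Arg1 and Ch25h lie above 0 on the horizontal and below 0 on the vertical axis.

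The largest falls with 9 libraries are given first. Lyz2 fell by 1.55 ± 0.0627 (SE) on the log2 scale, from 15817 ± 956 TPM (SD, n = 4) to 5406 ± 366 TPM (SD, n = 5), with a limma adjusted p of 5.7e-06. Arg1, the arginase of alternatively activated macrophages, fell from 533 ± 156 TPM (SD, n = 4) to 139 ± 98.5 TPM (SD, n = 5), a log2 fold change of -2.09 (limma adjusted p of 0.023). KO replicate 5 stood at 315 TPM for Arg1 and the other KO libraries at 92.2 to 96.3 TPM. Arg1 and Ch25h, the cholesterol 25-hydroxylase gene (log2 fold change -1.11), had positive log2 fold changes with all 12 libraries, 0.70 and 1.52, neither of which passed the threshold. The same held for the scavenger receptor gene Stab1 (-0.71 with 9 libraries, 0.51 with 12), the sialic acid receptor gene Siglec1 (-0.80 and 0.10), the glycosyltransferase gene B3gnt7 (-0.96 and 0.18) and the coagulation factor gene F13a1 (-0.76 and 0.83). Falls in the same direction in both sets were seen for Fn1 (fibronectin, -1.02), Cav1 (caveolin 1, -1.14), Cbr2 (-0.83), Gpr84 (-0.80), Atf5 (-0.79) and Gsta3 (-1.44), each with a limma adjusted p between 0.0054 and 0.046 with 9 libraries and none past the threshold with 12.

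Among the largest rises with 9 libraries was Lpl, the lipase that frees fatty acids from lipoproteins, from 549.6 ± 120 TPM (SD, n = 4) to 1049.6 ± 252 TPM (SD, n = 5), a log2 fold change of 0.92 (limma adjusted p of 0.041). Ccl2, the chemokine that attracts monocytes, rose from 608 ± 61.0 TPM (SD, n = 4) to 1169.9 ± 284 TPM (SD, n = 5), a log2 fold change of 0.91 (limma adjusted p of 0.028). The remaining genes among the 12 largest rises were Rac2 (0.90), Itgb7 (0.83), L1cam (0.64), Icam2 (0.68), Lyz1 (2.15), Cxcr3 (0.95), Tle6 (0.88), Fcho1 (0.88), Ap1s3 (0.75) and Ccl27a (0.74), all on the log2 scale. All 12 also had positive log2 fold changes with all 12 libraries, where only Lyz1 and Cxcr3 passed the threshold. The 9 libraries are part of the 12, so the shared sign is not independent support. WT replicates 2, 3 and 4 lay above all KO libraries for Tle6, Fcho1 and Itgb7, with 12-library values of 0.21, 0.11 and 0.30. They lay below all KO libraries for Lyz1, Cxcr3, Lpl, Ccl2, Ap1s3 and L1cam, and reached into the KO range for Rac2, Icam2 and Ccl27a. With the submission block and 9 libraries, Lpl, Ccl2, Tle6, Fcho1, Itgb7 and Ccl27a lost their calls, as did Cav1, Siglec1, Atf5 and F13a1 among the falls. Over the other settings run, that block included, the call was lost in 11 of 19 for Lpl, 12 of 19 for Itgb7 and 12 of 18 for Ccl27a.

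Several genes of the antioxidant response, a list made mostly of targets of the transcription factor Nrf2, were lower in KO. With 9 libraries, 5 of the 25 measured members fell and 1 rose over all genes tested, or 9 and 2 adjusted over the list alone. Gclm, the modifier subunit of the enzyme named above, fell from 451 ± 34.5 TPM (SD, n = 4) to 303 ± 11.6 TPM (SD, n = 5), a log2 fold change of -0.57 (limma adjusted p of 0.0023). Gclc (-0.32), Gsta3 (-1.44), the thioredoxin reductase gene Txnrd1 (-0.29) and the catalase gene Cat (-0.35) fell as well, and G6pdx, which supplies NADPH, rose by 0.30. The list test (camera with a preset correlation of 0.01) gave an adjusted p of 8.5e-08 with 9 libraries and 1.1e-08 with 12. With an estimated correlation the adjusted p was 0.958 and 0.921. In the set of 12 libraries 1 member fell (Gclc), or 5 fell and 1 rose adjusted over the list alone. The mean log2(TPM + 1) of the list was 7.58 to 7.60 in the KO libraries and 7.79 to 7.84 in WT replicates 1, 5 and 7, but 7.59 in WT replicate 6, inside the KO range. The list stood far above both groups in WT replicates 2, 3 and 4, at 8.85 in replicate 4 and higher in the other 2. Gsta3 stood at 291, 349 and 193 TPM in WT replicates 2, 3 and 4, against 6.86 to 14.6 TPM in the other WT libraries and 2.47 to 5.17 TPM in KO.

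Genes of the integrated stress response, which are driven by the transcription factor Atf4, had mostly negative log2 fold changes with 9 libraries, but the genotypes overlapped. Of 27 measured members, 25 had negative log2 fold changes, 3 fell and 1 rose over all genes tested, and 10 fell and 1 rose adjusted over the list alone. The members that fell were Slc7a5, an amino acid transporter gene (-0.33, limma adjusted p of 0.015), Sesn2 (-0.24, adjusted p of 0.031) and Atf5 (-0.79, adjusted p of 0.046), and Atf3 rose by 0.49 (adjusted p of 0.036). The mean log2(TPM + 1) of the list was 5.59 to 5.62 in WT replicates 1, 5 and 7 and 5.34 in WT replicate 6, below KO replicates 2, 3 and 5 at 5.44, 5.48 and 5.45. All of these lay below WT replicates 2, 3 and 4, at 5.78, 5.69 and 5.90. The lowest values were those of KO replicates 1 and 4, at 5.10 and 5.28, which also held the most S100a9, at 3507 and 2375 TPM. Camera gave an adjusted p of 1.2e-10 with 9 libraries and 7.0e-04 with 12, and 0.958 and 0.921 with an estimated correlation. Herpud1, of the unfolded protein response list, fell by 0.28 as 1 of its 22 measured members.

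Lists for lipid handling, sugar use and inflammation were examined next, with 9 libraries unless stated. Cholesterol biosynthesis genes were called lower by camera (adjusted p of 6.4e-04, or 0.958 with an estimated correlation), with a median log2 fold change of -0.06 and 0 of 23 members called. In the set of 12 libraries their median was 0.17 (adjusted p of 0.464). Of the cholesterol efflux list, Nceh1 (0.28) and Scd2 (0.40) rose among 19 members, though Scd2 was at -0.56 with 12 libraries. Of the glycolysis list, Hk1 (0.25), Hk3 (0.47) and Aldoc (0.49) rose while Hk2 (-0.28) and Eno1 (-0.16) fell, with a camera adjusted p of 0.401 for the list. In the inflammasome list, Ninj1 fell by 0.31 (limma adjusted p of 0.0032) and Naip2 by 0.30 (adjusted p of 0.044) among 21 members, though Naip2 was at 0.28 with 12 libraries. Ccl2 was the called member among 25 cytokine and NF-kappaB genes. Camera called that list lower in KO with 12 libraries (median log2 fold change -0.22, adjusted p of 0.028, or 0.921 with an estimated correlation) and did not call it with 9 (adjusted p of 0.258). Among immediate early genes, Zfp36 (0.46), Atf3, Dusp1 (0.46) and Nr4a1 (0.61) rose and Junb (-0.38) fell among 23 members. Of 45 interferon response genes none was called in either set, although 42 had positive log2 fold changes with 9 libraries and 39 with 12. Their mean log2(TPM + 1) was 3.78 to 4.03 in the KO libraries, 3.36 to 3.39 in WT replicates 1, 5 and 7 and 4.43 in WT replicate 6, above all KO libraries. WT replicates 2, 3 and 4 stood at 3.45, 3.25 and 2.68, below all KO libraries. Their median log2 fold change was 0.22 with 9 libraries (camera adjusted p of 0.098) and 0.53 with 12 (6.0e-04, or 0.921 with an estimated correlation). With 9 libraries, 8 of 21 other settings called the list higher, with a camera adjusted p of 9.0e-26 at the preset correlation without WT replicate 6. The estimated correlation of the list with 9 libraries was 0.833, far above the preset 0.01, and camera with it gave an adjusted p of 0.958. In the BAF complex list itself, Brd7 (0.18) and Bicral (0.39) rose among 25 members. Pcna, the sliding clamp of DNA replication, rose by 0.43 (adjusted p of 0.0045) as 1 of 46 proliferation genes. Of these 46, 44 had positive log2 fold changes with 9 libraries and 14 with 12, and camera called the list in neither set (adjusted p of 0.326 and 0.085). Other settings called it higher in 2 of 21 with 9 libraries and lower in 8 of 27 with 12. Called genes went both ways in the lists for alternative activation (Tgm2 0.33, Arg1 -2.09), complement (C3ar1 0.30, C1qc -0.26) and autophagy (Nbr1 0.23, Sqstm1 -0.22), and Itgb5 (-0.29) fell in the migration list. With 12 libraries C1qc was at 0.76 and Itgb5 at 0.36. Hypoxia genes were called lower by camera (adjusted p of 0.047, or 0.958 with an estimated correlation), with a median of -0.03, Arg1 alone called among 19 members and the call lost in 13 of 21 other settings. Over 19 other settings of the 9 libraries, Scd2 lost its call in 13, Hk1 and Tgm2 in 12, Nceh1, Naip2, Hk2, Dusp1, Nr4a1, Atf3, Brd7, Bicral, C1qc and C3ar1 in 11, and Eno1 and Sqstm1 in 10.

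Genes of mitochondrial function were compared next. Over 10 lists with 214 measured genes, 0 genes were called by limma with all 12 libraries (16 at an unadjusted p under 0.05) and 2 with 9 libraries (36 at an unadjusted p under 0.05). The 2 were Slc25a20, the mitochondrial carnitine carrier (0.27), and Sqstm1, a receptor of selective autophagy (-0.22). Camera on the 12 libraries called complex I (median log2 fold change -0.08, adjusted p of 6.0e-04), complexes II and III (-0.05, 0.028), complex IV (-0.11, 0.021), the tricarboxylic acid cycle (-0.08, 0.016), fatty acid oxidation (-0.11, 0.020) and mitochondrial ribosome proteins (-0.03, 0.018) lower in KO. The adjusted p was 0.921 for each of these with an estimated correlation. Without WT replicates 2, 3 and 4 none of the 10 lists was called, the lowest adjusted p was 0.415 and list medians lay between -0.01 and 0.06. Complexes II and III, the tricarboxylic acid cycle and fatty acid oxidation then turned from lower to higher. Over 27 other settings of the 12 libraries, these 3 lists lost their calls without turning in 10, 6 and 8. Complex I, complex IV and the mitochondrial ribosome proteins lost theirs in 5, 9 and 12. Transcripts encoded in the mitochondrial genome made up 1.41% ± 0.126 (SD, n = 5) of listed TPM in KO and 1.25% ± 0.254 (SD, n = 7) in WT, with an exact permutation p of 0.216. In WT replicate 4 the share was 0.691% and mt-Atp8 was listed at 0, against 3801 to 4936 TPM in the other libraries. Leaving mt-Atp8 out gave 0.934% ± 0.0874 (SD, n = 5) in KO and 0.854% ± 0.0917 (SD, n = 7) in WT, with an exact permutation p of 0.164.

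Markers of other cell types were examined because a marrow culture can hold several. Stromal markers of the 12 libraries were lower in KO (19 measured genes, median log2 fold change -0.96, camera adjusted p of 1.9e-04) and neutrophil markers higher (17 genes, median 1.87, adjusted p of 6.0e-04). Both gave an adjusted p of 0.921 with an estimated correlation, and no member of either was called over all genes tested. Adjusted over the list alone, 13 neutrophil genes were higher and 1 was lower. Without WT replicates 2, 3 and 4 the stromal list was not called (median 0.20, adjusted p of 0.851). The neutrophil list was called higher, with a median of 0.76 and a camera adjusted p of 0.047, or 0.958 with an estimated correlation. Of its 17 members 0 were called even adjusted over the list alone, and the list lost its call in 10 of 21 other settings. KO replicates 1 and 4 stood at 1910.3 and 1402 TPM for S100a8, against 320 to 637 TPM in the other KO libraries and 364 to 457 TPM in WT replicates 1, 5, 6 and 7. Macrophage markers were called lower with 9 libraries (19 genes, median -0.11, camera adjusted p of 2.8e-04, or 0.958 with an estimated correlation). The list was not tested without Lyz2, and the other 18 genes had a median of -0.0925, with 12 of them below 0. Within that list Lyz2 and C1qc fell, C1qc by 0.26 in contrast to 0.76 with 12 libraries, and Cd14 rose by 0.51. The calls of C1qc and Cd14 were lost in 11 and 12 of 19 other settings. In the set of 12 libraries this list was not called (median 0.24, adjusted p of 0.436).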

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

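The tests of WT replicates 2, 3 and 4 and of Lyz2 given here were chosen after the values were seen, apart from that of library scaling. Among 194 groups of values examined, 10 held a single library far from the others of its genotype, where chance alone would give about 9.7. The rule looks for 1 library at a time, so it passes over WT replicates 2, 3 and 4 where they stand apart together. The groups are mostly genes picked for the text and are not independent, so the 2 counts do not show that outlying libraries are at chance level. Of these 10, 6 were in WT replicate 4: Lyz2 at 5232 TPM (others 14635 to 21547), Csf2rb at 49.4 TPM (56.6 to 59.6), Pcna at 397 TPM (555 to 658), Cd36 at 747 TPM (958 to 1085), mt-Atp8 listed at 0 (4092 to 4936) and a mitochondrially encoded share of 0.691% (1.23 to 1.41). KO replicate 5 was high for Arg1 at 315 TPM (others 92.2 to 96.3) and low for Ripk3 at 27.7 TPM (32.7 to 34.1). WT replicate 6 was high for Ifit3 at 33.4 TPM (2.66 to 7.47), and WT replicate 5 was low for Cox6a1 at 765 TPM (813 to 836).

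WT replicates 2, 3 and 4 stood apart from the other 9 libraries. A lower share of macrophages would raise markers of all other cell types alike if these kept their proportions. In these libraries the stromal list lay 2.35 to 2.75 above the median of the other WT libraries, and the neutrophil list 2.09 to 2.15 below it. The gap of at least 4.49 on the log2 scale argues against a loss of macrophages with the other cells in constant proportion. More stromal cells in place of both macrophages and neutrophils could give the same gap, but would lower the macrophage markers alike. The lowest of that list, C1qa, shifted by -3.80, -2.47 and -4.16 on the log2 scale in WT replicates 2, 3 and 4. The highest shifted by 0.13 (Cd68), 0.44 (Lyz2) and -0.33 (Cd68). In the other WT libraries the list members shifted by -0.24 to 0.60. For these markers the spread argues against a lower share of macrophages alone. A lower share beside other changes stays open. KO libraries carrying a WT label are argued against by Smarcd1, whose lowest value in the 3 was 11.6 TPM, above the highest KO value of 7.58 TPM. A shift in library scaling is argued against by the spread of the genes, whose log2 ratios had an interquartile range of at least 0.632 while the median gene moved by at most 0.0581. A different culture or cell state of these 3 libraries stays open, since no label describes one and no biological explanation was tested.

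Lyz2 was lower in all 5 KO libraries than in 6 of the 7 WT libraries. Reads passing from Lyz2 to its near-identical neighbour Lyz1 would leave their sum level, but the sum changed by -1.54 on the log2 scale with 9 libraries, as much as Lyz2 (-1.55). A lower share of macrophages would lower the other macrophage markers alike, but the median of the other 18 was -0.0925 on the log2 scale, with an interquartile range of 0.236. A knockout made with a driver inserted at the Lyz2 locus, a common design for macrophages, could lower Lyz2 by itself. The labels do not give the construct, and with 1 WT library (replicate 4, 5232 TPM) in the KO range, that insertion and an effect of Smarcd1 loss cannot be told apart.

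The count of genes called rose from 14 to 260 when WT replicates 2, 3 and 4 were left out, and the 2 tests of this rise were written down before their results were seen. Removing 3 libraries was not sufficient by itself: over the 35 ways of leaving out 3 of the 7 WT libraries the median count was 3. Spread among the WT libraries may account for the rise, since the 30 ways that left 1 or 2 of these libraries in the WT group gave at most 53 genes. Of the 4 sets that kept WT replicates 2, 3 and 4 with 1 other library as the WT group, 3 gave 3025 to 3694 genes, and the one with WT replicate 6 gave 4.

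Random splits of the libraries, planned before their results were seen, were compared with the real one, over 100 splits each. Among the 12 libraries, 1 split, the real one, gave 14 genes or more, and the highest other gave 1. Among the 9 libraries, 1 split, the real one, gave 260 genes or more, and the highest other gave 27, so no other split reached either gene count. At an unadjusted p under 0.05 in limma, the real split of the 12 libraries gave 1954 genes and was not the highest. Other splits gave 2261, 4166 and 5193. With the 9 libraries the real split gave 2111 at that threshold, and the highest other 1754. Chance cannot be excluded for the number of lists called by camera at the preset correlation. With 12 libraries 58 splits gave 12 lists or more (highest other 25), and with 9 libraries 75 splits gave 6 lists or more (highest other 17).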

How the results depend on the processing

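Unless named as planned in the processing account, settings here were chosen after seeing the data. With all 12 libraries, where 14 genes were called, other settings gave 4 (median-ratio scaling), 759 (sample quality weights), 3 (submission block), 4317 (first residual component, which removes spread by construction), 89 (stromal covariate), 260 (without WT replicates 2, 3 and 4), 3 (adjusted p under 0.01) and 4 (at least 1.5-fold), and 2 to 36 with 1 library left out. No filter, a pseudocount of 0.1, both together, rescaling and a 5 TPM minimum gave 12 to 14. Of the 13 named genes called, 4, 3, 3 and 4 stayed called with median-ratio scaling, the submission block, adjusted p under 0.01 and 1.5-fold, and 2 to 13 with 1 library left out. Whether same-numbered libraries were paired is unknown. Their deviations from the means of their genotypes correlated at 0.222, 0.204, 0.135, -0.224 and -0.181, and in 1 of 5 cases a WT library matched its own number best. The WT mean includes WT replicates 2, 3 and 4, which shift the deviations of all WT libraries, so this check cannot decide on pairing. The replicate block on 10 libraries called 0 genes in limma (3706 at an unadjusted p under 0.05) and 0 of the 13, against 13 genes and 7 of the 13 in the same libraries without the block. Smarcd1 was then at -0.84 (adjusted p of 0.133), and it kept its call in every other setting run. Within this set no called named gene changed sign.

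Against 12 of 46 lists called with all 12 libraries, 0 of 46 were called with estimated correlation (0 at an unadjusted p under 0.05) or by fry (5 at an unadjusted p under 0.05). Quality weights and the stromal covariate called 5 each, and leaving out WT replicates 2, 3 and 4 called 6. Against 6 of 46 lists with 9 libraries, 0 of 46 were called with estimated correlation (1 at an unadjusted p under 0.05) or by fry (10 at an unadjusted p under 0.05), and the other settings gave 4 to 7. These fry counts are for members moving in 1 direction. The mixed fry test, for changes in either direction, passed for some lists with 9 libraries and not for others. Its adjusted p was 4.7e-08 for the glycolysis and macrophage lists and 0.428 for the interferon list. Component scores gave 1 of 3 past the threshold without the 3 libraries and 0 to 1 with 1 library left out. The mitochondrial share did not pass in any setting.

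With 9 libraries, the 260 genes became 170 (pseudocount 0.1 and no filter), 758 (quality weights), 132 (submission block), 936 (first residual component), 825 (stromal covariate), 30 (adjusted p under 0.01), 41 (1.5-fold) and 51 to 462 with 1 library left out. Of 57 named genes, 31 stayed called with no filter, 35 with a pseudocount of 0.1 and no filter, 29 with the submission block, 10 at adjusted p under 0.01, 27 at 1.5-fold and 12 to 49 with 1 library left out. The cause of these changes was not tested. The count models, the surrogate variable and the sex covariate were not run, and the planned stricter filter coincides with the one used. TPM holds no depth, so its limits on low genes are unknown.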

Other observations

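The genes and tests of this part were chosen after their values were seen. With 9 libraries, 2 genes of necroptosis, a lytic form of cell death, were higher in KO. Mlkl, the pore-forming effector, rose by 0.46 on the log2 scale (limma adjusted p of 0.011), and the kinase gene Ripk3 by 0.52 (adjusted p of 0.027). With all 12 libraries their log2 fold changes were 0.00 and -0.07, and WT replicates 2, 3 and 4 held 23.4 to 27.8 TPM of Mlkl and 47.7 to 76.2 TPM of Ripk3, above all KO libraries. The pattern receptor genes Tlr2 (-0.65, adjusted p of 0.029) and Tlr7 (-0.55, adjusted p of 0.033) fell with 9 libraries, as did the biliverdin reductase gene Blvrb (-0.42, adjusted p of 0.0023) and the phospholipase gene Pla2g7 (-0.72, adjusted p of 0.0023).

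Libraries within a genotype differed along markers of other cells. KO replicates 1 and 4 held 3507 and 2375 TPM of S100a9, against 536 to 1102 TPM in the other KO libraries, and 62.3 and 41.4 TPM of Mpo, against 11.1 to 23.0 TPM. WT replicate 6 held 117 TPM of the interferon-induced gene Isg15, against 34.9 to 42.6 TPM in WT replicates 1, 5 and 7, and 15.7 TPM of Col1a1, the lowest of the 12 libraries.

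A targeted allele carries flanking DNA of its strain of origin, and genes beside it may then differ for that reason. As a hypothesis, genes within 10 Mb of Lyz2 and of Smarcd1 were compared with all other tested genes, with Smarcd1, Lyz2 and Lyz1 left out. Whether the Lyz2 locus was targeted is not known from the labels. Near Lyz2, 3 of 63 genes were called with 9 libraries (4.76%, against 2.29% elsewhere), with a one-sided Fisher's exact p of 0.177. They were Mettl1, Osbpl8 and Tmem19. Near Smarcd1, 4 of 104 were called (3.85%, against 2.29%), with an exact p of 0.219. These were Soat2 and the genes Itgb7, Nr4a1 and Gpr84 given above. Both adjusted p-values were 0.219. The shares were higher at both loci but not beyond chance, and with so few genes neither locus can be excluded. Csf2rb2, Csf2rb and Rac2, all higher in KO with 9 libraries, also lie on chromosome 15, outside the window around Smarcd1. They start close together, at 78282507, 78325752 and 78559167. Whether flanking DNA reaches them was not tested.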
